A study of Gallus gallus with 8 samples.

How the data were processed

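Sinus tissue of 8 chickens (Gallus gallus) was profiled on 8 Agilent arrays with a single Cy3 channel. Per the labels' protocols, the tissue was excised at 21 weeks of age and kept in RNAlater. Total RNA was isolated with a fibrous tissue kit and treated with DNase on the column, and 100 ng per bird, with spiked control transcripts, was amplified and labelled with Cy3. The labels place 2 birds in each of 4 groups (control, mild, moderate and severe symptoms) and describe them as different birds. The p-values of single probes below therefore rest on the spread between the 2 birds of a group, pooled over all 4 groups and not taken from the compared groups alone.

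The deposited scanner files hold each spot's brightness as an intensity on a linear scale, made by Agilent Feature Extraction 10.7.3.1 per the file headers. Per the file headers, the processed intensity was background-subtracted and corrected for spatial trends within the array, with a substitute value for dim spots, and it was not normalized between arrays. The same deposited files hold the raw mean intensity, the median local background and 0-or-1 marks per spot for signal well above background, saturation and outliers. The deposited value table of the series holds log2 values. Its scale was found by setting each column against the scanner values of its own array: r was 0.9988 to 0.9999, against at most 0.983 with any other array. Every column had a median of 8.09 and the same distribution (sorted values differed by at most 0.005 between the 10th and 90th percentiles), so the table is quantile normalized. Its values ran from 1.22 to 19.3, and how they were scaled before that step, any floor and the filter that left 41172 probes in it are not given in the sources used here. No per-sample column was left unused (0 columns).

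Each array had 45220 spots, of which 43803 were not control spots. These spots held 43603 distinct 60-nt probes, and 50 probes with 5 spots each were averaged. The value analysed was the log2 of the processed intensity minus the 75th percentile of that array, so a level of 0 is the 75th percentile. Control spots and 8 to 60 spots per array marked as outliers were left out, and no spot was saturated. A probe was tested where it lay well above background on both arrays of at least 1 group, which left 39697 probes, 35200 of them well above background on all 8 arrays. The 75th percentile of the processed intensity ran from 840.5 to 1536 and the median from 185.5 to 305.3. The fit of the spiked transcripts had an r2 of 0.987 to 0.997, and probes spotted repeatedly had a coefficient of variation of 7.08% to 13.6%. The number of arrays limits the precision of every value.

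Probes were named from the deposited files and from the RefSeq gene table of chicken assembly GRCg7b (25635 genes), which was used for names only. A RefSeq accession named 14177 probes and a gene number 309. An older symbol was updated for 390 probes, 11240 probes already had a current symbol and 1569 kept the symbol of the array design. The other 15918 probes have no gene name here, and 27685 probes carried 13012 distinct symbols. Coordinates are those of the deposited files, build galGal3, counted from 1, and they mark the stretch a probe lies on rather than the whole gene. No genome sequence was used, so exons and untranslated regions were not assigned. Where a gene had several probes, the 1 with the highest mean signal over all arrays stands for it, which gave 12323 genes, and the text says where other probes of a named gene pointed the other way.

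Group means were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (data.table package version 1.17.8), with 4 residual degrees of freedom and moderated variances (prior 2.77 degrees of freedom, prior SD 0.366 log2). The 7 contrasts were each symptom group against control, the mean of the 3 symptom groups against control (called infected against control), and the 3 differences between symptom groups. P-values were adjusted with Benjamini-Hochberg over all probes of a contrast and called at an adjusted p under 0.05. Where a probe was not well above background on any array of a group, only a bound is given: the brighter group's mean against the mean of, per array, the lowest signal well above background or the probe's own signal if that was higher. Such folds are written "at least N-fold".

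Before the data were examined, 25 gene lists (878 entries, 716 of them measured, 12 genes in more than 1 list) were fixed, covering immune genes, resident and invading cell types, energy metabolism, the cell cycle and stress. Members were matched by current symbol or by the array design's symbol. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with p-values adjusted over the 25 lists of a contrast. That test sets the statistics of a list's genes against those of all other genes. At this preset the members count as nearly independent, so its p-value rests mainly on the spread between genes, not between birds. Camera with the correlation estimated from the data, and fry, which asks whether a list's genes move one way on balance, were alternatives. Counts "adjusted over the list alone" use only the members of that list.

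Named genes follow a rule fixed at the same time. For each contrast with control it takes the 12 largest rises and 12 largest falls among genes with a symbol in standard form that passed the test and lay on 1 side of both control arrays on every symptom array. For the contrasts between symptom groups it takes up to 5 in each direction, with the smallest p where fewer pass. It adds up to 4 members with the smallest p from each list and reference genes (GAPDH, ACTB, TBP, RPL13 and YWHAZ are reported). Probes named outside this rule are said to have been chosen after their values were seen.

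The scanner files place the arrays on 2 slides, each scanned once and each holding 1 array of every group. Counts are given with the slide as a block, and values within each slide. Other alternatives were normexp background correction (offset 50), quantile normalization, median centring, the deposited value table, other filters on dim probes, outlier spots kept, an intensity trend or robust prior, array weights, the replicate number as a block, fits to only the groups compared, 1 value per gene, at least 2-fold change, an adjusted p under 0.1, and leaving out each array in turn. Fits without probes of chromosomes W and Z, and normexp without spots whose local background exceeded 1000, were chosen after seeing the data.

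The fit was tested on simulated data: 39697 probes, 200 of them changed, 50 at each size, in 10 runs. Each probe's variance was drawn from the prior of the fit and was the same in all groups. The real groups differed in spread (array weights 2.65 for control and 0.444 for severe arrays). The shares below therefore hold for groups of equal spread. For infected against control, 0% of changes of 1 log2 unit were recovered, 30% of 2 units, 83.2% of 4 units and 95.2% of 6 units, and 5.19% of calls were false. For mild against control the shares were 0.2%, 9.6%, 75.8% and 90.8%, with 4.75% of calls false. None of the recovered probes had the wrong direction (0 probes). In a simulation over the 12323 genes, the skeletal muscle list was lowered by 1 log2 unit in infected against control. Camera called that list in 10 of 10 runs, 9 of 10 with the estimated correlation, and called 0 of 240 tests of other lists. The simulated genes varied independently, so these runs cannot show how camera behaves on correlated genes. In the data the macrophage list had an estimated correlation of 0.741 in mild against control. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with tables handled in pandas 2.3.3 and numpy 2.4.6.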

Results

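Infectious coryza is an acute disease of the upper airways of chickens caused by the bacterium Avibacterium paragallinarum. The study screened sinus tissue for immune genes regulated during infection with serovar C-3 of this bacterium. Of 15 leghorn birds obtained at 10 weeks of age, 12 were challenged with 0.1 ml of bacteria in the infra-orbital area and 3 were left unchallenged. Symptoms were scored 1 (mild), 2 (moderate) or 3 (severe). Arrays were made from 2 birds of each score and 2 unchallenged birds, all at 21 weeks and all described as male. Between 82.96% (moderate replicate 1) and 91.13% (severe replicate 2) of spots lay well above background.

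On component 1 of a principal component analysis (52.8% of the variance) the arrays labelled control scored -148 and -142, and 5 of the 6 infected arrays scored 16.8 to 128. Severe replicate 1 scored -100, on the control side. Its correlation over probes was 0.959 with control replicate 1 and 0.924 with the other severe array. The inflammatory cytokine and chemokine list had a median log2 level, relative to the control mean, of -0.07 on severe replicate 1 and of 1.19 to 2.97 on the other infected arrays. The skeletal muscle list stood at -0.37 on severe replicate 1 and at -2.39 to -1.03 on the others.

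**Figure D1:**
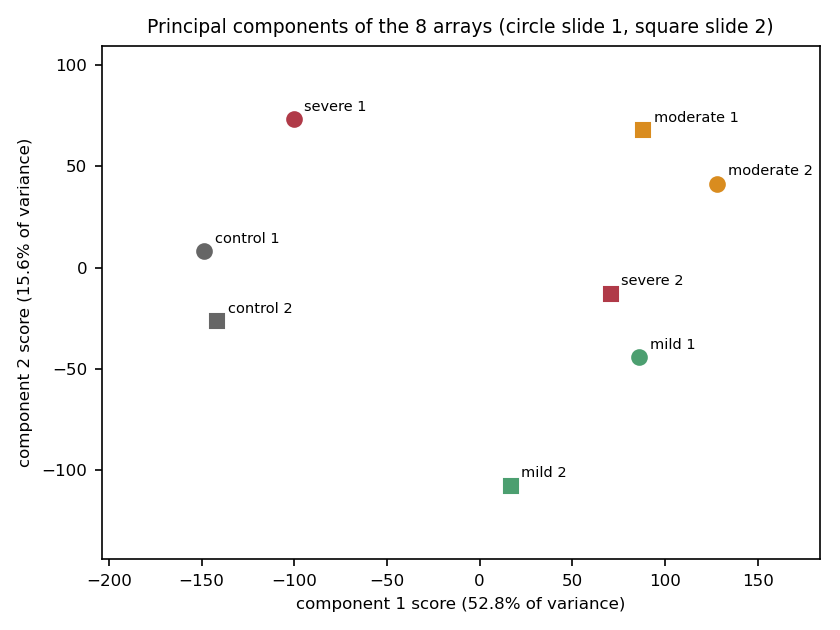
Scores of the 8 arrays on principal components 1 (52.8% of the variance) and 2 (15.6%), coloured by symptom group, circles for slide 1 and squares for slide 2. Both control arrays (-148 and -142) and severe replicate 1 (-100) lie left of 0 on component 1 and the other infected arrays (16.8 to 128) right of it.

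The arrays labelled control also differed from all infected arrays in the sex chromosomes. In birds, females carry 1 Z and 1 W chromosome and males carry a Z pair. All 51 tested W probes lay well above background on both control arrays, and 27 of them were lower in infected birds by limma's test, 0 higher. Of the 51 W probes, 7 were not well above background on any infected array. HINTW, a W-linked gene, fell at 8 of 8 probes. One of them was not well above background on any infected array, so no size is given for it. The others changed by -11.70 to -1.69 log2 units. The probe at W_random 581356 to 581415 changed by -11.70 log2 units (SE 0.23, limma adjusted p = 2.1e-05, lower on 6 of 6 infected arrays). ATP5F1AW, the W copy of a mitochondrial ATP synthase subunit gene (W_random 579696 to 579755), changed by -9.62 (SE 0.41, limma adjusted p = 2.2e-04). Severe replicate 1 shared this: over all W probes its median was -1.14 against the control mean, and the other infected arrays had -2.23 to -1.62. The 1631 Z probes had a median log2 change of 0.22, and the 27 autosomes with at least 200 probes had medians of -0.28 to -0.07. Every comparison with control below therefore also compares arrays that differed in W and Z signal.

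**Figure D2:**
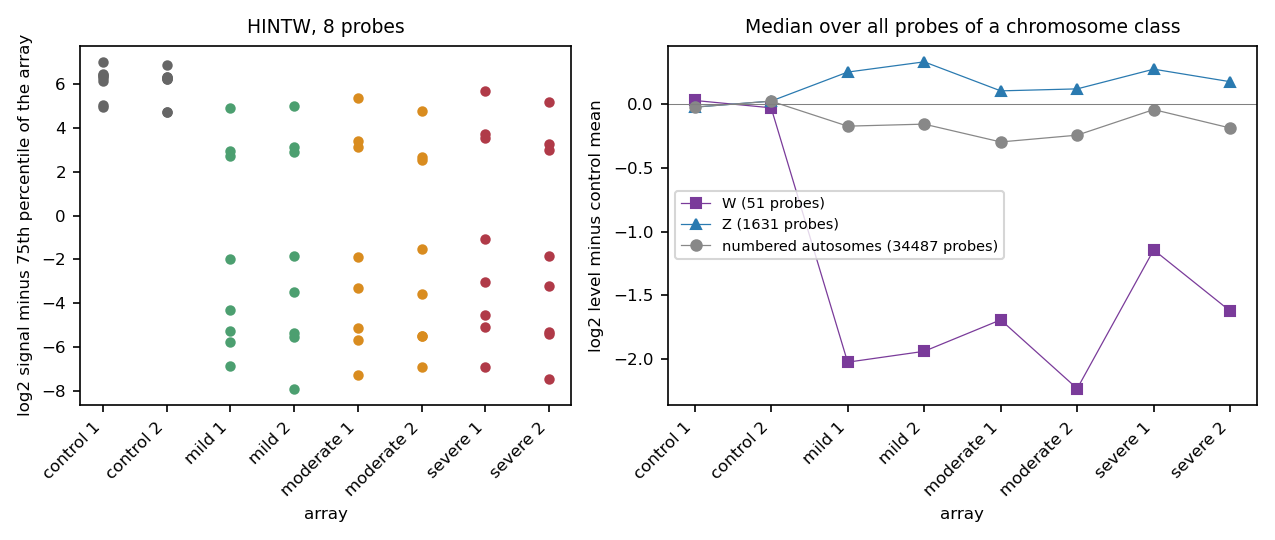
Left, log2 signal minus the 75th percentile of the array for the 8 HINTW probes on each array. Right, median log2 level minus the control mean over 51 W, 1631 Z and 34487 autosomal probes: W medians lie between -2.23 and -1.14 on the 6 infected arrays.

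Infected against control asked which genes differed between the sinus of birds with symptoms and that of unchallenged birds, as the mean of the 3 symptom groups (6 arrays) against the 2 arrays labelled control. EXFABP, a lipocalin that binds bacterial siderophores (chromosome 17, 881182 to 881804), rose by 5.20 log2 units (SE 0.88, limma adjusted p = 0.0385, 36.8-fold). ACOD1, the itaconate-producing enzyme of activated macrophages (chromosome 1, 158569966 to 158570025), rose by 5.85 (SE 1.11, adjusted p = 0.0477), and HPX, a haem-binding plasma protein, by 4.47 (SE 0.65, adjusted p = 0.0302). These were 3 of the 33 measured antimicrobial and acute-phase genes to pass, all upward (5 adjusted over the list alone). The list's median was 0.69 (0.91 and 0.59 within slides 1 and 2, camera adjusted p = 0.0069), with adjusted p = 0.566 with an estimated correlation. The estimated-correlation value is 0.566 for every list of this comparison called below unless another is printed.

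Marker lists of heterophils and macrophages were higher, though cells were not counted here. The heterophil and granulocyte list had a median of 2.36 (2.04 and 2.67 within slides, camera adjusted p = 2.5e-07), with adjusted p = 0.566 with an estimated correlation. Of its 18 measured members 3 rose and 0 fell (8 rose adjusted over the list alone). They were CEBPB, a transcription factor of myeloid cells and the acute-phase response (3.26, SE 0.27, adjusted p = 0.00556), the calgranulin S100A12 (4.28, SE 0.70, adjusted p = 0.0365) and SERPINB10B (4.35, SE 0.76, adjusted p = 0.04, 1 of its 3 other probes pointed the other way). The macrophage and monocyte list had a median of 1.97 (camera adjusted p = 7.9e-07) and 1 of 22 members rose, HMOX1, the haem-degrading oxygenase (4.36, SE 0.59, adjusted p = 0.0264, chromosome 1, 54135746 to 54135805). On severe replicate 1 these lists stood at 0.36 and -0.19, and on the other 5 infected arrays at 1.51 to 4.02 and 1.52 to 3.06.

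The pattern recognition and NF-kB list had a median of 1.30 (1.12 and 1.20 within slides, camera adjusted p = 6.7e-10), and 2 of its 42 members rose (10 adjusted over the list alone). They were the feedback inhibitor SOCS3 (3.56, SE 0.47, adjusted p = 0.0243) and NFKBIZ, an IkB-family regulator (2.97, SE 0.51, adjusted p = 0.0397). Interferon-stimulated genes had a median of 1.83 (camera adjusted p = 2.2e-08). None of the 29 passed over all probes (0 rose), and 20 rose and 1 fell adjusted over the list alone. For inflammatory cytokines and chemokines the median was 1.35 (camera adjusted p = 2.0e-04), with 0 of 30 members past the test and 4 adjusted over the list alone. IL1B stood at 2.60 (adjusted p = 0.0542) and the chemokine IL8L1 at 4.26 (adjusted p = 0.067). MHC and antigen presentation genes had a median of 1.06 (camera adjusted p = 1.2e-05; 0 of 23 past, 4 adjusted over the list alone). All 4 lists had adjusted p = 0.566 with an estimated correlation, and all stood between -0.14 and 0.03 on severe replicate 1.

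T and NK cell markers had a median of 0.53 (0 of 25 past, camera adjusted p = 0.0175), with adjusted p = 0.704 with an estimated correlation. The arrays differed in sign, at 1.23 and 0.88 on the mild, -0.66 and 0.55 on the moderate and -0.45 and 1.67 on the severe arrays. B and plasma cell markers had a median of 0.39 (camera adjusted p = 0.0954). Their 1 member to rise was CD72, a lectin of B cells, which was not well above background on the control arrays and was at least 94.0-fold higher (adjusted p = 0.0161); its only other probe pointed the other way. Complement and coagulation genes had a median of 0.09, a mean of 0.78 and 0 of 23 past (5 up and 1 down adjusted over the list alone, camera adjusted p = 0.0352), with adjusted p = 0.566 with an estimated correlation.

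Genes of muscle and mitochondria were lower in infected birds. The skeletal muscle list had a median of -1.59 (-1.38 and -1.62 within slides, camera adjusted p = 2.3e-04), and 4 of 42 members fell and 0 rose (21 down and 2 up adjusted over the list alone). They were the fast troponin TNNI2 (-1.73, SE 0.30, adjusted p = 0.04), the muscle enolase ENO3 (-3.14, SE 0.55, adjusted p = 0.0408), the myosin light chain MYLPF (-2.15, SE 0.41, adjusted p = 0.0484) and the muscle caveolin CAV3 (-3.71, SE 0.71, adjusted p = 0.049). MYOM2, a sarcomere M-band protein outside the list, fell as well (-4.02, SE 0.60, adjusted p = 0.031). The oxidative phosphorylation list had a median of -1.27 (-1.17 and -1.40 within slides, camera adjusted p = 1.2e-09). NDUFS1, a complex I subunit, was the 1 of 48 members to pass (-2.24, SE 0.43, adjusted p = 0.0484), and 42 fell and 1 rose adjusted over the list alone. Both lists had adjusted p = 0.566 with an estimated correlation. On severe replicate 1 the oxidative phosphorylation list stood at -0.17, and on the other infected arrays at -1.63 to -1.27. Cartilage and bone genes had a median of -0.64 (camera adjusted p = 0.0171, adjusted p = 0.566 with an estimated correlation, fry adjusted p = 0.0424) and 3 of 21 fell: ACAN, the cartilage proteoglycan (at least 1.60-fold, adjusted p = 0.0355), RUNX2, a bone regulator (-1.74, adjusted p = 0.0387) and osteocalcin, BGLAP (-1.19, adjusted p = 0.0448).

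Of 30 immediate early and heat shock genes 4 rose and 0 fell (8 adjusted over the list alone; median 0.37, camera adjusted p = 1.7e-04, adjusted p = 0.566 with an estimated correlation, fry adjusted p = 0.0441). They were the small heat shock protein HSPB9 (4.93, SE 0.54), HSPH1 (2.49, SE 0.27) and MYC (2.16, SE 0.24), each with adjusted p = 0.0145, and the antiproliferative gene BTG2 (1.79, SE 0.25, adjusted p = 0.0264). Cell cycle genes had a median of 0.41 (camera adjusted p = 0.0171), with adjusted p = 0.733 with an estimated correlation, and 1 of 45 rose, the replication helicase subunit MCM2 (1.19, SE 0.22, adjusted p = 0.0442). The arrays differed in sign: cell cycle medians were below control on both moderate arrays (-0.49 and -0.69) and severe replicate 1 (-0.45), and moderate against control had a median of -0.51 with 34 of 45 lower (camera adjusted p = 0.628). Outside the lists, rises included RUNX1, a transcription factor of blood cell formation (5.19, SE 0.38, adjusted p = 0.00314, chromosome 1, 109473604 to 109473663), the small GTPase RRAD (5.64, SE 0.49, adjusted p = 0.00697) and CDKN1A, the p21 inhibitor of the cell cycle (4.62, SE 0.51, adjusted p = 0.0151). The necroptosis kinase RIPK3 rose by 4.37 (SE 0.48, adjusted p = 0.0145) and AVD, the biotin-binding protein avidin, by 6.57 (SE 0.95, adjusted p = 0.0296, 1 of 3 other probes pointed the other way).

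**Figure D3:**
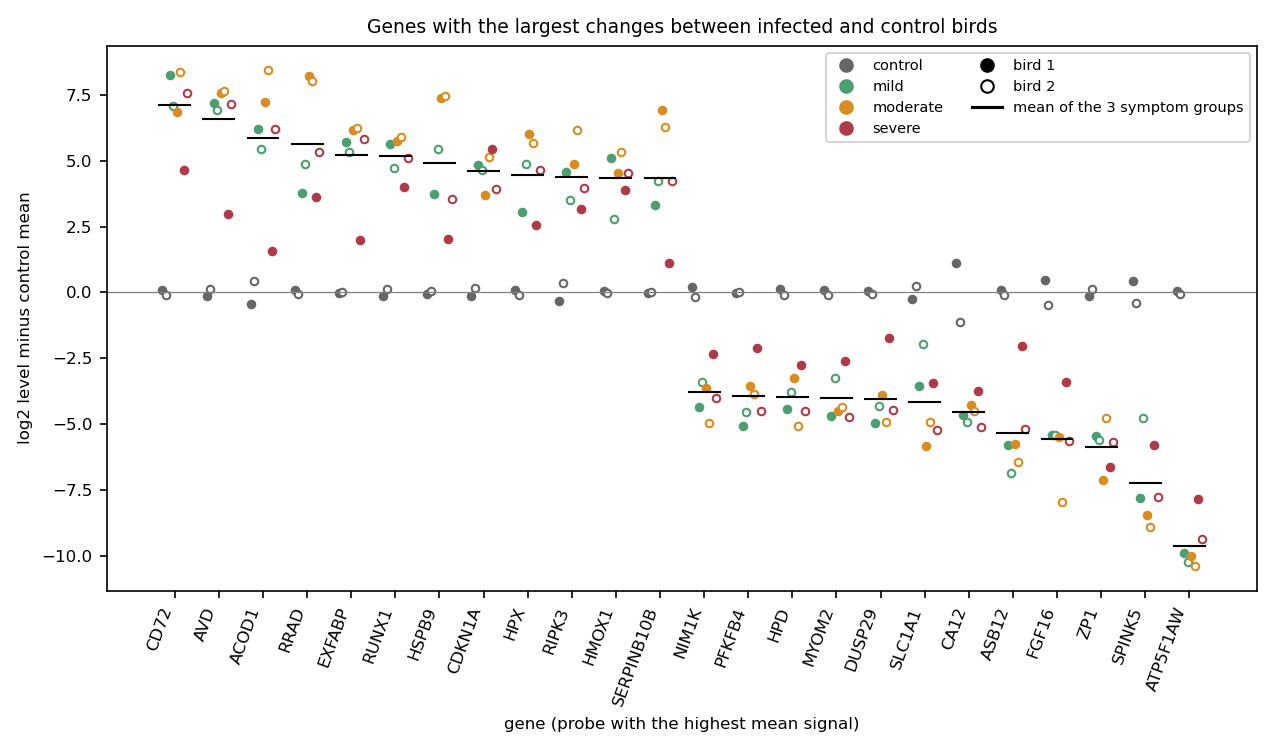
Log2 level minus the control mean of the genes with the largest changes in infected against control birds, a point per array (filled, bird 1; open, bird 2) and a bar for the mean of the 3 symptom groups. RUNX1 lies at 4.01 to 5.91 on all 6 infected arrays, and ACOD1, EXFABP and AVD are lowest on severe replicate 1.

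The largest falls beside W-linked genes were in SPINK5, a protease inhibitor (-7.25, SE 0.85, adjusted p = 0.0177, chromosome 13, 10623546 to 10624080), and ZP1, an egg-coat glycoprotein (-5.87, SE 0.59, adjusted p = 0.0117). FGF16, a growth factor, fell by 5.55 (SE 0.79, adjusted p = 0.0282), and ASB12, a ubiquitin ligase adaptor, by 5.34 (SE 0.79, adjusted p = 0.0306). The carbonic anhydrase CA12 was at least 6.90-fold lower (adjusted p = 0.0264). SLC1A1, DUSP29, HPD, PFKFB4 and NIM1K fell by 4.15, 4.05, 3.96, 3.94 and 3.78, with 2 of 3 other PFKFB4 probes pointing the other way. Motile cilium genes had a median of -0.36 (camera adjusted p = 0.0586), and TPPP3 (-2.66, adjusted p = 0.0142) and CFAP70 (-2.65, adjusted p = 0.0276) were the 2 of 28 to fall.

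Other lists of this comparison had no camera call. Their medians were -0.55 for fibroblast and collagen genes (0 of 31 past), -0.58 for epithelial and mucous genes, -0.70 for nerve genes (NEFH fell by 1.86), -0.61 for erythrocyte genes, -0.18 for endothelium (0 of 23), -0.85 for smooth muscle (0 of 16) and -0.23 for glycolysis and hypoxia (fry adjusted p = 0.0441). Epithelial FOXA2 fell by 1.76 (its other probe pointed the other way) and TP63 rose by 2.29. The glycolytic enzyme PGAM1 fell by 1.35, and PDK4, which restrains pyruvate oxidation, rose by 3.21. Among erythrocyte genes GYPC fell by 2.29 and the haem-synthesis enzyme FECH rose by 1.41. Matrix metalloproteinases had a median of -0.09 and a mean of 0.79 (0 of 19 past), and the median turned positive with quantile normalization, median centring and the deposited table (0.03, 0.00 and 0.04). Adipocyte and lipid genes had a median of -0.07, 0.02 with median centring, and a mean of 0.06. Of these 28 genes CIDEA (3.16), PLIN2 (2.18) and ACSL1 (1.49) rose and ADIPOQ fell (-1.54).

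**Figure D4:**
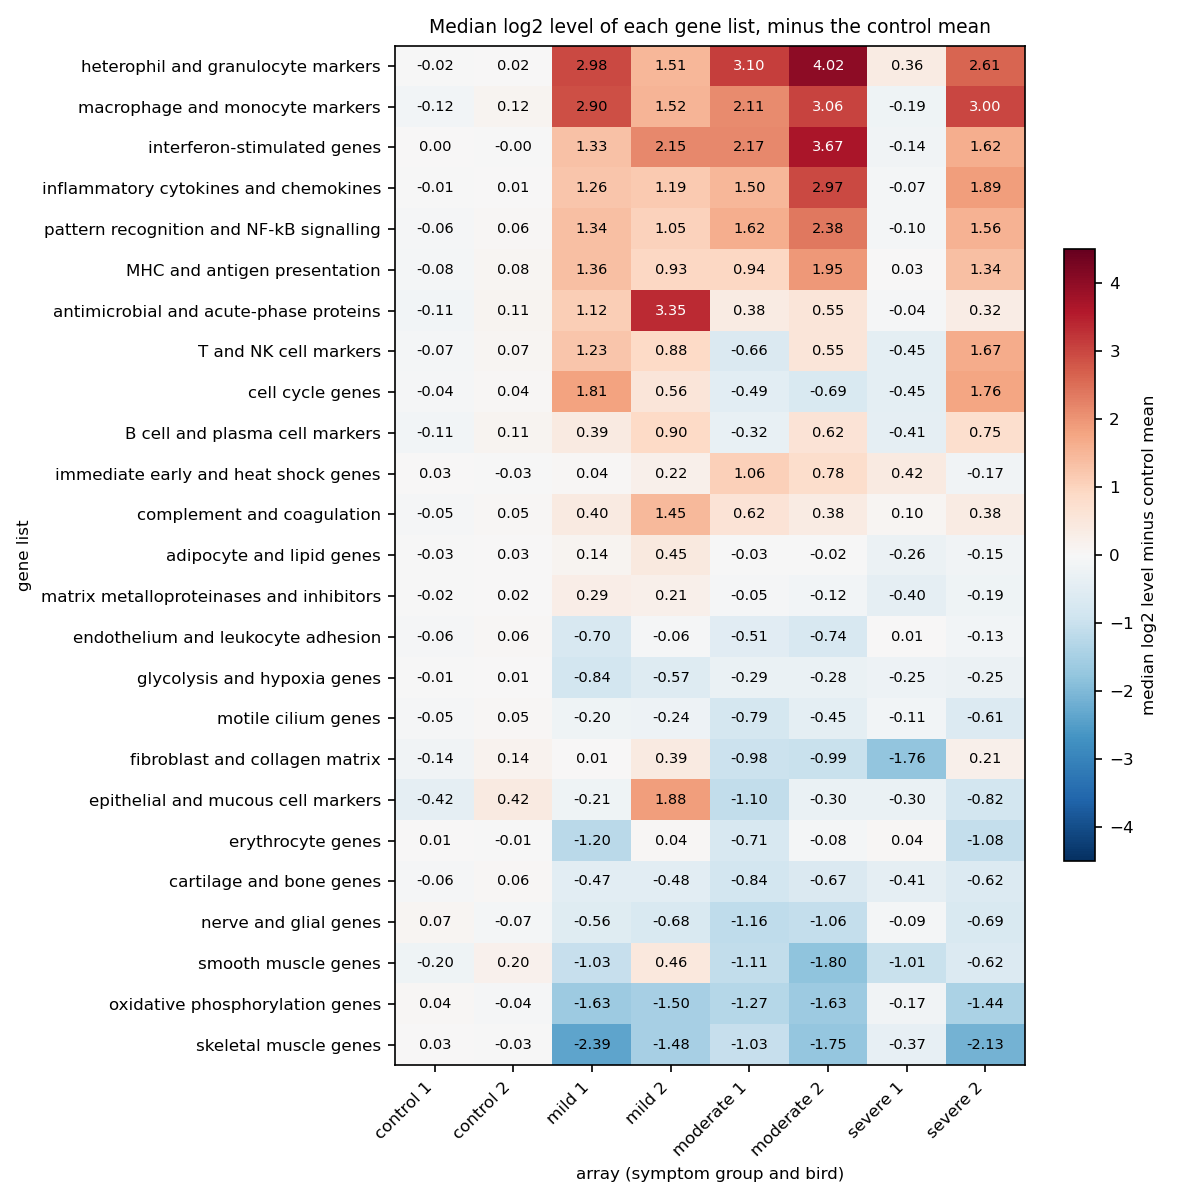
Median log2 level of the 25 gene lists on each array, minus the mean of the control arrays; colour and printed value show the same quantity. Heterophil markers stand at 0.36 on severe replicate 1 and at 1.51 to 4.02 on the other infected arrays; the direction of the infected medians turned with another scaling for matrix metalloproteinase and adipocyte genes.

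In all, limma called 1169 of 39696 probes in infected against control, 409 higher and 760 lower (401 genes, 150 higher and 251 lower); the smallest adjusted p was 2.1e-05. All probes had a median change of -0.18 log2 units (-0.03 with quantile normalization), which the scaling sets, and changes are relative to it. The lower share of calls was 65.0%, against 52.3% with quantile normalization, 55.0% with median centring and 52.3% in the deposited table. W probes gave 27 of the calls and Z probes 118 (86 higher, 32 lower), and 840 probes passed without W and Z. The calls were 7.23% of the Z probes tested, against 2.67% of the probes on numbered autosomes. Genes named above without a chromosome may lie on Z, where a change cannot be told from the difference in Z signal. With the slide as a block 285 probes passed. The count was 34 or 38 without control replicate 1 or 2, 233 without mild replicate 1, 198 or 159 without moderate replicate 1 or 2, and 9473 or 2906 without severe replicate 1 or 2.

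In moderate symptoms against control, genes of inflammation passed the test singly. MMP9, the gelatinase of heterophil granules, rose by 10.05 log2 units (SE 1.92, limma adjusted p = 0.041, chromosome 20, 10532805 to 10532864), and NOS2, the inducible nitric oxide synthase, by 8.08 (SE 1.38, adjusted p = 0.0351, chromosome 19, 9162853 to 9162912). Of 30 cytokine and chemokine genes 4 rose and 0 fell (13 adjusted over the list alone). IL1B, a pyrogenic cytokine, rose by 4.60 (SE 0.66, adjusted p = 0.0262) and IL8L1, a heterophil attractant, by 6.64 (SE 1.24, adjusted p = 0.0399). The amino acid oxidase IL4I1 was at least 329-fold higher (adjusted p = 0.043), and the chemokine CCL20 at least 115-fold (adjusted p = 0.0471). The list's median was 2.54 (3.45 and 1.62 within slides 1 and 2, camera adjusted p = 7.1e-06), with adjusted p = 0.599 with an estimated correlation.

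Interferon-stimulated genes had a median of 2.72 (3.67 and 2.13 within slides, camera adjusted p = 4.0e-11), and 9 of 29 rose and 0 fell (22 adjusted over the list alone). Among them were the RNA sensor IFIH1 (3.73, SE 0.65, adjusted p = 0.0359) and viperin, RSAD2 (6.10, SE 1.16, adjusted p = 0.0403). Of 42 pattern recognition and NF-kB genes 8 rose and 0 fell (22 adjusted over the list alone; median 2.03, camera adjusted p = 4.6e-12). SOCS3 rose by 4.97, the adaptor MYD88 by 2.67 and the decoy receptor IL1R2 by 3.97. Heterophil markers had a median of 3.55 (6 of 18 rose, 13 adjusted over the list alone, camera adjusted p = 1.1e-08), with S100A12 at 6.38 (SE 0.85, adjusted p = 0.0231). Macrophage markers had a median of 2.53 (2 of 22 rose, 6 adjusted over the list alone, camera adjusted p = 6.1e-07). For MHC genes it was 1.38 (camera adjusted p = 3.8e-06), and the peptide transporter subunit TAP1 rose by 3.47 (1 of 23 past, 8 adjusted over the list alone). Antimicrobial genes had a median of 0.27 (camera adjusted p = 0.0138) and 4 of 33 rose, EXFABP by 6.20, ACOD1 by 7.84 and HPX by 5.84 beside NOS2 (7 up and 1 down adjusted over the list alone). Each of these lists had adjusted p = 0.599 with an estimated correlation.

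Immediate early and heat shock genes had a median of 0.78 (0.73 and 1.02 within slides), and 8 of 30 rose (11 adjusted over the list alone), among them HSPH1 (3.90, SE 0.33, adjusted p = 0.00677) and KLF6 (1.83, SE 0.25, adjusted p = 0.0241). Camera gave adjusted p = 2.7e-08, with adjusted p = 0.319 with an estimated correlation, and fry adjusted p = 0.0112. Muscle genes had a median of -1.55 (camera adjusted p = 0.00557, adjusted p = 0.711 with an estimated correlation), with 4 of 42 down and 1 up (12 and 1 adjusted over the list alone). The 1 that rose was ANKRD1, a stress-responsive ankyrin repeat protein (5.95, SE 1.15, adjusted p = 0.0415). Myostatin, MSTN, a brake on muscle growth outside the list, fell by 4.63 (SE 0.44, adjusted p = 0.00874). Beside the muscle genes, oxidative phosphorylation genes had a median of -1.46 (1 of 48 fell, 41 adjusted over the list alone, camera adjusted p = 1.9e-08). Cilium genes had a median of -0.65 (2 of 28 fell, 6 adjusted over the list alone, camera adjusted p = 0.0138) and cartilage genes of -0.69 (4 of 21 fell, 7 adjusted over the list alone, camera adjusted p = 0.029, fry adjusted p = 0.0199). These 3 lists had adjusted p = 0.599 with an estimated correlation.

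Matrix genes included falls in the proteoglycans BGN (-3.76, SE 0.51, adjusted p = 0.0242) and LUM (-4.10, SE 0.76, adjusted p = 0.0398) and in FBN1 (-1.39, adjusted p = 0.0491), the 3 of 31 fibroblast and collagen genes to pass (median -1.01, camera adjusted p = 0.0686). MMP2 fell by 2.23 while MMP9 rose. The median of T and NK cell markers was -0.03, and 0.14 to 0.16 with quantile normalization, median centring and the deposited table (camera adjusted p = 0.544). B cell genes had a median of -0.11 that also turned positive under those scalings. Glycolysis genes had a median of -0.34, 0.01 with quantile normalization, and a mean of 0.10; ALDOC rose by 3.32 and SLC2A14 by 3.66.

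Limma called 2438 probes in moderate against control, 935 higher and 1503 lower (806 genes), with a median change over all probes of -0.28. The lower share was 61.6%, against 46.6% with quantile normalization, 44.3% with median centring and 46.6% in the deposited table. W probes gave 29 calls and Z probes 173. With the slide as a block 546 probes passed; the count was 23 or 32 without control replicate 1 or 2, 89 or 34 without moderate replicate 1 or 2, and 8753 without either severe array.

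Mild symptoms against control gave fewer single-gene calls. RUNX1 rose by 5.18 log2 units (SE 0.46, limma adjusted p = 0.0119), CDKN1A by 4.75 (SE 0.63, adjusted p = 0.046) and XDH, the urate-forming xanthine dehydrogenase, by 4.32 (SE 0.59, adjusted p = 0.0489). The metallothionein MT3 rose by 3.93 (SE 0.36, adjusted p = 0.0134, chromosome 11, 2102802 to 2102861) and AEN, a p53-induced nuclease, by 3.82 (SE 0.28, adjusted p = 0.00456, chromosome 10, 14819960 to 14820019). CEBPB rose by 2.94, the lipid droplet protein CIDEA by 3.48, and the lectin-like receptor CLC2DL5 by 3.05 (SE 0.28, adjusted p = 0.0141). CD72 was at least 135-fold higher (adjusted p = 0.0445). Falls included MSTN (-3.38, SE 0.44, adjusted p = 0.0451), the glycogen-targeting subunit PPP1R3C (-3.50, SE 0.36, adjusted p = 0.0221), the intermediate filament protein SYNC (-2.70, adjusted p = 0.047) and ZP1 (-5.51, adjusted p = 0.046).

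Immune lists were high in the mild group without many single calls. Medians were 2.42 for heterophil (1 of 18 rose, 3 adjusted over the list alone, camera adjusted p = 2.4e-06), 2.27 for macrophage (0 of 22, 1 adjusted over the list alone; 1.6e-06), 2.06 for antimicrobial (0 of 33, 4 up and 1 down adjusted over the list alone; 1.4e-04) and 1.86 for interferon-stimulated genes (0 of 29; 8.0e-07). NF-kB genes had a median of 1.43 (0 of 42, 2 adjusted over the list alone, camera adjusted p = 5.7e-08), complement genes of 1.27 (0.0227), MHC genes of 1.06 (5.1e-05), T and NK markers of 1.06 (2.1e-04), cytokines of 1.05 (0.00245) and B cell genes of 0.61 (0.0447), and CD72 was the 1 member of these lists to rise. Cell cycle genes had a median of 1.12, 1.89 and 0.44 within slides 1 and 2 (camera adjusted p = 8.5e-06). Oxidative phosphorylation genes had a median of -1.54 (43 of 48 fell adjusted over the list alone, 0 over all probes, camera adjusted p = 3.2e-11), beside muscle genes at -1.89 (18 down and 1 up adjusted over the list alone; 3.3e-05). Glycolysis genes had a median of -0.70 (camera adjusted p = 0.0471, fry adjusted p = 0.0234), and the immediate early genes, 1 of which rose (MYC, 2.16), of 0.12 (0.0447), with -0.08 and 0.32 within slides. All of these lists had adjusted p = 0.506 with an estimated correlation.

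In mild against control 152 probes passed limma's test, 50 higher and 102 lower (41 genes), with a median change of -0.17; 67.1% of calls were lower, against 56.7% in the deposited table. W probes gave 19 of the calls, and 75 probes passed without W and Z. The slide block left 68. Without control replicate 1 or 2 the count was 23 or 28, without mild replicate 1 or 2 it was 44 or 63, without either moderate array 64 and without either severe array 4812.

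Severe symptoms against control rested on a pair of unlike arrays. RUNX1 rose by 4.56 log2 units (SE 0.46, limma adjusted p = 0.0211), MT3 by 4.52 (SE 0.36, adjusted p = 0.00677), AEN by 3.42 (SE 0.28, adjusted p = 0.00763), CEBPB by 2.97 (SE 0.33, adjusted p = 0.0337) and the oxidoreductase AIFM2 by 2.95 (SE 0.32, adjusted p = 0.0282). PPRC1, a coactivator of mitochondrial biogenesis, rose by 2.17 (adjusted p = 0.0496). Falls were ATP5F1AW, ZP1 (-6.14, adjusted p = 0.0441), ERNI (-3.60, adjusted p = 0.0177), the galactosyltransferase B3GALT2 (-3.09, adjusted p = 0.0104), TPPP3 (-2.93, adjusted p = 0.0447) and heparin cofactor II, SERPIND1 (-2.59, adjusted p = 0.0413). These values held on both slides: RUNX1 was at 4.15 and 4.97, MT3 at 5.12 and 3.92 and AEN at 3.59 and 3.25 within slides 1 and 2.

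The lists differed between the severe arrays. Within slide 1, which holds severe replicate 1, and slide 2, the medians were 0.09 and 2.80 for heterophil, -0.11 and 2.87 for macrophage, -0.01 and 1.75 for cytokine, -0.09 and 1.64 for interferon-stimulated, and -0.05 and 1.46 for NF-kB genes. Pooled medians were 1.29 (camera adjusted p = 4.4e-04), 1.27 (4.4e-04), 0.65 (0.0207), 0.73 (0.00312) and 0.67 (5.4e-05), and CEBPB was the 1 member of these lists to rise. Muscle genes stood at -0.34 and -2.16 within slides (pooled -1.29, camera adjusted p = 4.4e-04) and oxidative phosphorylation genes at -0.18 and -1.42 (pooled -0.84; 4.5e-06). Fibroblast genes went the other way, at -1.75 and 0.03 (pooled -0.70; 0.00564), and cell cycle genes stood at -0.41 and 1.80 (pooled 0.61; 0.0012). T and NK markers stood at -0.36 and 1.66 (pooled 0.54; 0.0207), with adjusted p = 0.65 with an estimated correlation. Other pooled medians were 0.73 for MHC (0.0012), -0.51 for epithelial (0.013), -0.26 for cilium (0.0253, TPPP3 fell), -0.46 for cartilage (0.00435; 4 fell adjusted over the list alone) and 0.05 for immediate early genes (0.0163; 4 rose adjusted over the list alone, 0.42 and -0.02 within slides). The other lists of this paragraph had adjusted p = 0.649 with an estimated correlation. Without severe replicate 2 camera called 4 of the 25 lists, against 15 with all arrays.

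Limma called 82 probes in severe against control, 18 higher and 64 lower (18 genes), 19 of them on W; 42 passed without W and Z and 58 with the slide as a block. All probes had a median change of -0.10. The lower share was 78.0%, against 60% with quantile normalization and 62.6% in the deposited table. The count was 25 or 27 without control replicate 1 or 2 and 753 without severe replicate 1.

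Moderate against mild asked what differed between these scores, and the W and Z chromosomes gave 0 calls. CLC2DL5 was lower in the moderate group (-3.39, SE 0.28, limma adjusted p = 0.0382, unplaced sequence), as was MXRA8, a matrix adhesion protein (-3.46, SE 0.31, adjusted p = 0.0496, chromosome 21, 2248221 to 2248280). The zinc finger gene ZFP3 was not well above background in the mild group and was at least 1.81-fold higher in the moderate one (adjusted p = 0.0382). Immediate early and heat shock genes were higher at 29 of 30 members (median 0.68; 0.69 and 0.73 within slides; 0 rose over all probes, 5 adjusted over the list alone). Camera gave adjusted p = 1.9e-10, with adjusted p = 0.102 with an estimated correlation, and fry adjusted p = 0.0396. Cell cycle genes were lower at 42 of 45 (median -1.45; -2.36 and -0.71 within slides; 0 fell over all probes, 3 adjusted over the list alone, camera adjusted p = 1.9e-10), with adjusted p = 0.628 with an estimated correlation. Interferon-stimulated (median 1.14, 2.23 and 0.22 within slides, camera adjusted p = 3.3e-06), heterophil (1.21, 2.0e-04) and cytokine genes (0.80, 8.6e-04) were higher and fibroblast (-1.14, 3.3e-06) and epithelial genes (-1.22, 1.6e-04, with -0.06 and -1.77 within slides) lower in the moderate group, with 0 members past over all probes and adjusted p = 0.628 with an estimated correlation.

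For glycolysis and hypoxia genes the median was 0.62 (camera adjusted p = 3.7e-05), with adjusted p = 0.102 with an estimated correlation. T and NK markers had a median of -0.91 (3.6e-04), with adjusted p = 0.724 with an estimated correlation, and NF-kB genes of 0.75 (6.4e-05), with adjusted p = 0.715. Cilium genes had a median of -0.33 that turned to 0.09 with normexp without spots of high background (camera adjusted p = 0.0013, adjusted p = 0.628 with an estimated correlation). In all 13 probes passed limma's test between moderate and mild, 3 higher and 10 lower, and 10 of them were not the probe that stood for a gene. The lower share was 76.9%, and 62.5% of 8 probes with median centring. With the slide as a block 1 probe passed. The count was 0 without either control, either moderate array or mild replicate 2, 3 without mild replicate 1 and 8 without either severe array.

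Severe against mild gave 3 probes, 0 higher and 3 lower, with an unadjusted p under 0.05 at 2224 probes where 1985 are expected by chance. They were chosen here after their values were seen: a probe of SSR3, a subunit of the translocon-associated complex (-5.31, SE 0.26, limma adjusted p = 0.00909, chromosome 9, 24451654 to 24451713), and 2 without a gene name that were not well above background in the severe group (chromosome 5, 15864424 to 15864483, at least 3.40-fold lower, and chromosome 1, 105102851 to 105102910, at least 6.83-fold lower). By the rule for genes none passed: PHC3 was at 3.65 (adjusted p = 0.166) and CLC2DL5 at -2.64 (adjusted p = 0.134). Oxidative phosphorylation genes were higher at 46 of 48 (median 0.81, 1.49 and 0.13 within slides, camera adjusted p = 3.7e-09). Epithelial (-1.57, 1.8e-07, with 0.08 and -1.42 within slides), fibroblast (-1.29, 1.8e-07), antimicrobial (-1.38, 5.65e-06) and interferon-stimulated genes (-0.95, 5.65e-06) were lower in the severe group, as were NF-kB (-0.63, 1.5e-04), macrophage (-0.81, 0.00191), heterophil (-0.97, 0.00252), T and NK (-0.61, 0.0034), cell cycle (-0.51, 0.00358), MHC (-0.27, 0.0138), metalloproteinase (-0.45, 0.0138), cytokine (-0.43, 0.0309) and adipocyte genes (-0.30, 0.0309). Muscle genes had a median of 0.76 (0.0045). Many of these medians turned sign on slide 2, away from severe replicate 1. Within slides 1 and 2 they were -2.75 and 1.05 for heterophil, -3.07 and 1.38 for macrophage, -1.70 and 0.47 for NF-kB, -1.65 and 0.87 for T and NK, -1.29 and 0.69 for cytokine and -1.03 and 0.36 for MHC genes. They were -2.37 and 1.28 for cell cycle, -0.65 and 0.21 for metalloproteinase and 1.89 and -0.32 for muscle genes. Against the control mean, fibroblast genes stood at -1.76 and 0.21 on severe replicates 1 and 2 and at 0.006 and 0.39 on the mild arrays. Interferon-stimulated genes stood at -0.14 and 1.62 on the severe and at 1.33 and 2.15 on the mild arrays. For antimicrobial genes these values were -0.04 and 0.32, and 1.12 and 3.35. These lists had 0 members past over all probes and adjusted p = 0.617 with an estimated correlation. The slide block, either control, mild replicate 2 or severe replicate 1 left out gave 0 probes, and leaving out severe replicate 2 gave 17.

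Severe against moderate gave 0 probes by limma, with a smallest adjusted p of 0.218 and 5026 probes at an unadjusted p under 0.05 (1985 expected by chance). ZFP3, not well above background in the severe group, was at least 2.05-fold lower there (adjusted p = 0.218), with the DNA repair gene BRCA2 at 2.67 and the transcription factor KLF6 at -1.83 (both adjusted p = 0.25). Interferon-stimulated genes were lower in the severe group at 28 of 29 members (median -1.95; 16 fell adjusted over the list alone, camera adjusted p = 3.9e-14), heterophil markers at 16 of 18 (-2.29; 5 adjusted over the list alone; 1.25e-08) and NF-kB genes at 39 of 42 (-1.37, 7.0e-12), each with adjusted p = 0.607 with an estimated correlation. Within slides 1 and 2 these medians were -3.82 and -0.48, -4.11 and -0.62, and -2.48 and -0.06, with severe replicate 1 on slide 1. Immediate early genes had a median of -0.51 (7 fell adjusted over the list alone, camera adjusted p = 1.9e-09, adjusted p = 0.239 with an estimated correlation). Cell cycle genes were higher at 40 of 45 (median 1.18, 3 rose adjusted over the list alone, camera adjusted p = 1.8e-04, adjusted p = 0.691 with an estimated correlation). Against the control mean they stood at -0.45 on severe replicate 1 and 1.76 on severe replicate 2, and at -0.49 and -0.69 on the moderate arrays. Oxidative phosphorylation genes were higher at 47 of 48 (0.65, 1.9e-05), and macrophage (-1.11, 1.2e-04) and MHC genes (-0.57, 1.9e-04) lower, with adjusted p = 0.691 with an estimated correlation. These 3 turned sign on slide 2: they stood at 1.44 and -0.06, -3.16 and 0.64, and -1.94 and 0.53 within slides 1 and 2. Cytokine (-1.30, 1.8e-06) and antimicrobial genes (-0.62, 0.00214) had 0.607 and glycolysis genes (-0.36, 0.0159) 0.53. Without severe replicate 2 the count of probes was 1907.

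The reference genes GAPDH, ACTB, TBP, RPL13 and YWHAZ did not pass in any comparison with control. In infected against control GAPDH stood at -0.70 (adjusted p = 0.159), ACTB at 0.88 (0.26, 3 of its 7 other probes pointed the other way), YWHAZ at 0.69 (0.261), TBP at 0.26 (0.467), and RPL13 at -0.24 (0.533), which turned to 0.19 with quantile normalization and 0.18 in the deposited table.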

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

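Differences between birds with different symptom scores were flagged because both groups compared were infected and the labels give no difference between them but the score. Moderate against mild gave 13 probes past limma's test. Among the genes of the naming rule, CLC2DL5 changed by -3.39 log2 units and MXRA8 by -3.46 in moderate against mild. ZFP3 was not well above background in the mild group, so its fitted 3.17 stands only as at least 1.81-fold higher. Severe against mild gave 3 probes. Each was tested by the difference itself and none by a further test.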

How the results depend on the processing

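The counts rest on 2 arrays per group, with the residual spread of all groups pooled, so each pair is assumed to vary like the others. Array weights were 2.65 for control, 0.938 for mild, 0.906 for moderate and 0.444 for severe arrays. Of 18 other settings, the probe count stayed within 1.5 times in 8 for mild, 11 for moderate, 12 for severe and 12 for infected against control, 8 for moderate against mild, 7 for severe against mild and 18 for severe against moderate. Every called probe changed at least 2-fold, so that setting altered no count. For severe against moderate the count was 0 in all 18. List counts with all arrays were 15, 12, 15, 14, 11, 15 and 11 in the same order, and of 14 other settings 12, 12, 12, 12, 11, 12 and 12 kept them within 1.5 times. Robust variance moderation does not enter camera. The replicate number names different birds: arrays sharing a number had correlations of -0.22 to 0.22 once group means were removed. Of 170 passing named values, 57 passed with the slide block, 99 with the replicate block, 4 or 5 without a control array, 26 or 32 without a moderate array, 79 or 95 without a mild array, 157 or 167 without a severe array, 0 with planned normexp, 148 with quantile normalization and 153 with normexp without spots of high background. The fits without W and Z probes and without spots of high background were chosen after seeing the data.

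Counts are given in the order mild, moderate, severe and infected against control, moderate against mild, severe against mild. Planned normexp gave 0, 0, 0, 8, 0 and 0 probes. It left moderate replicate 2 with a 10th percentile of -0.36, against -4.43 to -3.69 elsewhere; 22 spots with local background above 1000 were all on that array. Under it RUNX2 stood at 0.26, ACAN at 1.41 and NEFH at 0.36 in moderate against control, the other direction, with no call, and moderate against mild gave 5 lists. Without those spots normexp gave 395 probes for mild against control and 0 for moderate and for severe against mild. Quantile normalization gave 6 for severe against mild and median centring 8 for moderate against mild. Probes above background on all 8 arrays gave 34 for mild and 24 for severe against control, and 0 and 0 for the score contrasts. An intensity trend gave 2 and 1 for the score contrasts. Array weights gave 7124, 11861 and 12052 for mild, moderate and infected against control and 1 for severe against mild. The replicate block gave 90, 1346, 597, 1 and 0, and the slide block 68, 546, 285, 1 and 0, severe against control left aside. Only the groups compared gave 3994, 10528, 30 for the single groups, and 0 and 0 for the score contrasts. With 1 value per gene there were 25, 977, 26, 407, 0 and 0, and at an adjusted p under 0.1 there were 1803, 8709, 203, 6024, 31 and 7. Without W and Z probes mild gave 75 and severe 42. Camera with an estimated correlation called 0 lists in all 7 contrasts, and fry 1, 2, 0 and 3 against control, then 1, 0 and 0.

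Leaving out each array in turn gave 23 to 4812 probes for mild, 23 to 8753 for moderate, 25 to 753 for severe and 34 to 9473 for infected against control, 0 to 8 for moderate against mild, 0 to 17 for severe against mild and 0 to 1907 for severe against moderate. Lists ran from 12 to 16, 11 to 14, 4 to 16, 13 to 16, 9 to 13, 7 to 17 and 11 to 16. For severe against mild camera called 7 lists without severe replicate 1 and 9 without mild replicate 1, not necessarily the same ones. Leaving out either severe array removes that pair from the residual spread, and the mild and moderate counts against control rose while that of moderate against mild fell to 8. The causes of the other moves were not tested.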

Other observations

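Some single probes separated mild from the other scores, chosen here after their values were seen. A probe of SSR3 (chromosome 9, 24451654 to 24451713) was at -1.27 and -1.18 on the mild arrays and at -7.23 to -6.39 on the other 6 arrays (at least 34.7-fold lower in moderate than in mild birds, adjusted p = 0.00456). A probe of SBDS, a ribosome maturation factor (chromosome 19, 784640 to 784699), was higher in moderate than in mild birds (5.46, SE 0.44, adjusted p = 0.0352), near -6 on control and mild arrays. TOLLIP, a brake on Toll-like receptor signalling, had a probe that was at least 2.96-fold higher (adjusted p = 0.0352). The brightest probes of SSR3 and SBDS showed 0.34 (adjusted p = 0.776) and 0.07 (adjusted p = 0.975) in the same comparison.

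The tests of the next pattern were chosen after seeing the result. The median over W probes was lower on all 6 infected arrays than on the arrays labelled control. If the control birds were female and the infected birds male, Z probes should be higher: the Z median lay 0.290 log2 units above the highest autosome median, as such a difference in sex would give. A slide batch was set aside, since W probes were lower within both slides and the smaller median was -1.70. A fall of W transcripts with inflammation stays open. Severe replicate 1, with little inflammation, had 0.842 of the fall of the others over the 34 W probes called without it, but a smaller share over all 51 (-1.14 against -1.91), and it is a single array.

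For the array of severe replicate 1 the first 3 tests were chosen after seeing the result, and the share of moved probes before it was computed. For a swap with a control array, both control arrays kept the W signal and severe replicate 1 did not. It stood at -3.78 against the control mean over the 34 W probes called without it and at -1.14 over all 51. This speaks against a swap only if W signal went with being unchallenged, which the labels do not show. Neither control array lay among the infected arrays on component 1, at -148 and -142 against 16.8 to 128 for the infected arrays other than severe replicate 1. A dim array was set aside, with 90.2% of its spots well above background, and a slide batch too, since the lowest component 1 score of the other infected arrays on its slide was 86.1. An unchallenged bird under the severe label could not be told from a challenged one: of the 8037 autosomal probes called without it, 25.4% moved the same way by over 0.5 of the change and 2211 moved the other way, with a median share of 0.234.

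For genes raised on every infected array, severe replicate 1 included (RUNX1, RRAD, CDKN1A, AEN, AIFM2, PDK4, MT3 and MT4), the genes were picked after their values were seen and the tests, on genes not seen before, fixed before they were run. Genes of denervated or unused muscle left the question open (n = 21 genes, 10 higher, camera p = 0.665). So did p53 targets (n = 25 genes, 15 higher, camera p = 0.153). Glucocorticoid-induced genes went the other way (n = 18 genes, 1 higher, camera p = 0.00781 downward, 0.303 with an estimated correlation). The sex of the birds may also raise these genes and stays untested here.

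For the count of probes in infected against control, the test was fixed before it was run. Of the 28 ways to set 2 arrays against 6, 1 reached the real count of 788 in a fit to these 2 groups, and the highest other gave 11. The real split thus gave the highest count, the best rank that 28 splits allow. It is also the split by W and Z signal. The rank therefore cannot tell infection from that difference or from the choice of birds.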
